A study of Mus musculus with 6 samples.

How the data were processed

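Liver tissue from male C57BL/6 mice was fixed in formalin and embedded in paraffin, and regions were dissected from serial sections with the AVENIO Millisect instrument, per the labels' protocols. The mice had received the liver carcinogen diethylnitrosamine (DEN) at 25 mg/kg body weight at the age of 14 days. The samples are 3 regions of normal adjacent tissue and 3 glycogen-rich regions labelled as small tumours, with an age label of 7 months. Total RNA was depleted of ribosomal RNA, fragmented, and made into libraries from about 500 ng with 15 cycles of PCR, per the labels' protocols. Molecular identifiers are not named there, so counts are of reads, and counting error understates the error from PCR copies.

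Per the submitters' processing notes, which give no role or order, the tools were CASAVA 1.8, cutadapt 1.18, STAR 2.5.2b and DESeq2 1.24.0, with the mm10 build of the mouse genome. The counting tool, its annotation and its strand setting are not given in the sources used here. Reads of a gene and of an overlapping antisense gene could therefore share a count, and families of near-identical copies (Mup, Cyp2c, Saa, Serpina1, histone and class I histocompatibility genes) are uncertain member by member. The authors deposited whole-number counts per Entrez gene for each library. They also deposited FPKM values, in which each count is divided by gene length and by a scaled library size. Over genes with a count in every library, the ratio of count to FPKM between any 2 libraries was 1 constant. The authors' deposited table of the lesion against adjacent comparison holds a log2 fold change, its standard error, a test score and p-values for each gene. The table covers 25230 genes, of which 74 have no symbol and 18337 have at least 1 count in some library.

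Total counts per library were 6352898, 6495695 and 6542997 in normal adjacent regions 1 to 3 and 7294716, 7412833 and 7368314 in lesion regions 1 to 3. Genes kept by edgeR's expression filter with its defaults were tested, which left 12506 genes. Library sizes were scaled by the trimmed mean of M values (TMM). The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), two-sided, with robust dispersion estimates, the group as the only term and Benjamini-Hochberg adjustment over all tested genes. A gene passed at an adjusted p under 0.05. Standard errors of log2 fold changes were taken as the fold change divided by the square root of the F statistic. Levels are given as CPM on TMM-scaled library sizes, as mean ± SD over 3 libraries. Coordinates are those of the RefSeq gene table for GRCm38.p6, the assembly behind mm10, matched on Entrez identifiers for 12501 of the tested genes.

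A set of 50 gene lists was fixed, and 1107 of their 1132 symbols were in the table. Lists with at least 5 tested genes, 44 in all, were tested with camera (limma 3.58.1) against the other genes at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 44 lists. Two-sided camera with an estimated correlation and fry were the alternatives. For each list the members past the gene threshold were counted, and beside them the members past it when adjusted over the list alone. With an estimated correlation, 1 list remained higher (immediate early and heat shock genes) and 4 remained lower (male-biased genes, cytochrome P450 enzymes, pericentral genes, and bile acid genes). These 4 are not independent. In that order, 8 of 26, 13 of 31, 8 of 26 and 3 of 19 tested members also stand in another list.

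The genes named in the text follow a rule of 3 parts. The first part takes, in each direction, the 8 largest changes among passing genes with a mean of at least 5 CPM and all 3 lesion libraries beyond all normal libraries, without predicted genes, pseudogenes and small RNAs. Genes without a symbol were also left out there, which changed 0 of the picks. The second part is 12 genes of glycogen handling, the Hippo pathway and liver tumours. The third part takes up to 4 passing members of each list with the lowest p, or up to 2 members with the highest level where none passed. The rule named 188 tested genes, of which 181 passed, and genes outside it are said to be so. Some of the genes it named are not reported here. The lists, this rule, the tests and the alternatives were chosen before the data were examined, apart from those said in the text to have been added afterwards.

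The alternatives were other scalings (RLE, upper quartile and library size alone), 2 other count filters (none, or at least 20 counts in 3 libraries), small and ribosomal RNA left out, DESeq2 1.42.0, limma-voom, a fit that was not robust, and limma-trend on log2 FPKM with pseudocounts of 1 and 0.1. The FPKM fits kept genes with a mean of at least 0.5, or all genes. Further alternatives were the replicate number as a block, a loess correction for gene length with a span of 0.5, other thresholds, and each library and each replicate number left out in turn. The labels do not say which mouse each region came from. Their design text speaks of corresponding normal regions without tying a replicate number to a mouse, so the main fit was unpaired. Regions may share an animal, and p-values then measure only the spread between these samples and are too small if regions of a group share a mouse. Gene length was taken from the ratio of count to FPKM.

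The gene and list tests were checked on simulated counts for 12342 of the tested genes, drawn at the means, library sizes and dispersions of these libraries with 200 genes changed. In that simulation of lesion against normal adjacent, 44 of 67 genes changed 1.5-fold were recovered (65.7%), 57 of 67 changed 2-fold (85.1%) and 66 of 66 changed 4-fold. Of 182 simulated calls, 15 were unchanged genes and 0 of the changed genes had the wrong sign. A simulated list of 20 genes raised 1.5-fold gave a camera p of 4.2e-32 and an unchanged list a p of 0.33. The changed genes were picked among those with a mean of at least 5 CPM, so the recovery rates do not cover lower genes. Far fewer genes were changed than were called in the data, so the share of unchanged genes among the calls need not carry over. Genes were drawn independently there, so the simulation does not show how the list test does where genes of a list vary together.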

Results

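Transcripts were counted in 6 dissected liver regions of DEN-treated male mice, 3 early glycogen-rich lesions and 3 regions of normal adjacent tissue. The comparison asks which transcripts differ between lesions in which glycogen has piled up and the normal liver beside them. Totals ran from 6352898 to 6542997 counts in the normal libraries and from 7294716 to 7412833 in the lesion libraries. Between 16114 and 16407 genes had at least 1 count in a library. Regions were chosen by stacked glycogen, and no other criterion is given in the sources used here. The labels do not tie regions to animals, so every p-value measures the spread between these samples only and is too small if regions of a group share a mouse.

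As lists, genes of cell division, RAS response, fatty acid and cholesterol synthesis and fetal liver and tumour markers tested as higher in the lesions than in the normal regions. Lists of the urea cycle, drug metabolism, bile acid handling, mitochondrial respiration and male-biased liver proteins tested as lower. With an estimated correlation the drug metabolism, bile acid and male-biased lists kept their calls (adjusted p = 0.0135, 0.0213 and 0.0135), and the others named here lost theirs (adjusted p from 0.0733 to 0.422). Of 12506 genes tested with edgeR, 2340 (18.7%) were higher and 2296 (18.4%) lower in the lesions. Among these, 541 rose and 303 fell by at least 1 on the log2 scale. All lesion libraries lay beyond all normal libraries in 2219 of the higher and 2225 of the lower genes, and in 48.2% of all tested genes. Chance gives 10% if the 6 libraries are independent, and more if regions of a group share a mouse or an RNA sample. The first principal component, with 68% of the variance of log2 CPM, separated the groups. The second, with 13%, separated lesion 3 (-29.1) from lesions 1 and 2 (13.1 and 13.9). Albumin mRNA (Alb) took 3.37% to 3.72% of normal and 7.25% to 8.84% of lesion counts. The ribosomal precursor Rn45s took 10.6% to 12.7% and 11.8% to 14.7%. With library size alone as the scale, the median of all genes shifted by -0.14 on the log2 scale, and 1474 genes were higher and 3615 lower. The higher share of calls was then 29% against 50.5%, so changes in this text are relative to the TMM scale.

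The largest rises were in genes that are almost silent in the normal regions. H19 (Entrez 14955, chromosome 7, 142575530 to 142578146), an imprinted non-coding RNA of fetal liver, went from 1.77 ± 0.393 CPM to 1567 ± 972 CPM. Its log2 fold change was 9.77 (SE 1.16, edgeR adjusted p = 0.00424), with 2220, 2032 and 450.3 CPM in lesions 1 to 3. The H19 call was lost without replicate 1 or replicate 2 of both groups (edgeR adjusted p = 0.087 and 0.0965) and with the closest libraries summed (normal 2 with 3 and lesion 1 with 2), an alternative chosen after seeing the data (edgeR adjusted p = 0.0831). Tff3, a secreted trefoil peptide, rose by 6.43 on the log2 scale (SE 0.631, edgeR adjusted p = 0.00202). Fgf21 (Entrez 56636, chromosome 7, 45613890 to 45615490), a hepatic hormone of the fasting and stress responses, went from 0.245 ± 0.166 to 18.7 ± 3.05 CPM (log2 6.15, SE 0.321, edgeR adjusted p = 1.12e-11). The adaptor gene Shc2 rose by 6.05, the immunoglobulin-superfamily gene Igdcc4 by 5.88 and the synaptic gene Rims2 by 5.91 on the log2 scale. Phgdh and Psat1, which encode the opening enzymes of serine synthesis, rose by 5.89 and 5.01. The normal regions held 36 H19 counts, 17 Tff3 counts and 5 to 12 counts of each of the other genes over 3 libraries, so these folds are loosely set. The Phgdh call was lost without normal 1, 2 or 3 (edgeR adjusted p = 0.0609, 0.0601 and 0.0521). The Rims2 call was lost without any 1 library except lesion 3 (edgeR adjusted p from 0.0907 to 0.127).

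The largest falls were in secreted urinary proteins and detoxifying enzymes. The major urinary protein genes Mup2, Mup13, Mup8, Mup15 and Mup1 had log2 fold changes from -2.21 to -1.88, with Mup2 going from 729.6 ± 70.3 to 157.8 ± 10.2 CPM (edgeR adjusted p = 1.23e-13). These near-identical copies can share reads and are uncertain singly. Not every Mup gene fell: of the 6 tested in the list of male-biased genes, 5 were lower and 1 was higher. Etnppl (Entrez 71760, chromosome 3, 130617448 to 130635750), which degrades phosphoethanolamine, fell by 1.96 on the log2 scale (SE 0.0727, edgeR adjusted p = 1.07e-13). The cytochrome P450 gene Cyp2c37 fell by 1.88 and the sulfotransferase gene Sult2a8 by 1.85 on the log2 scale.

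**Figure D1:**
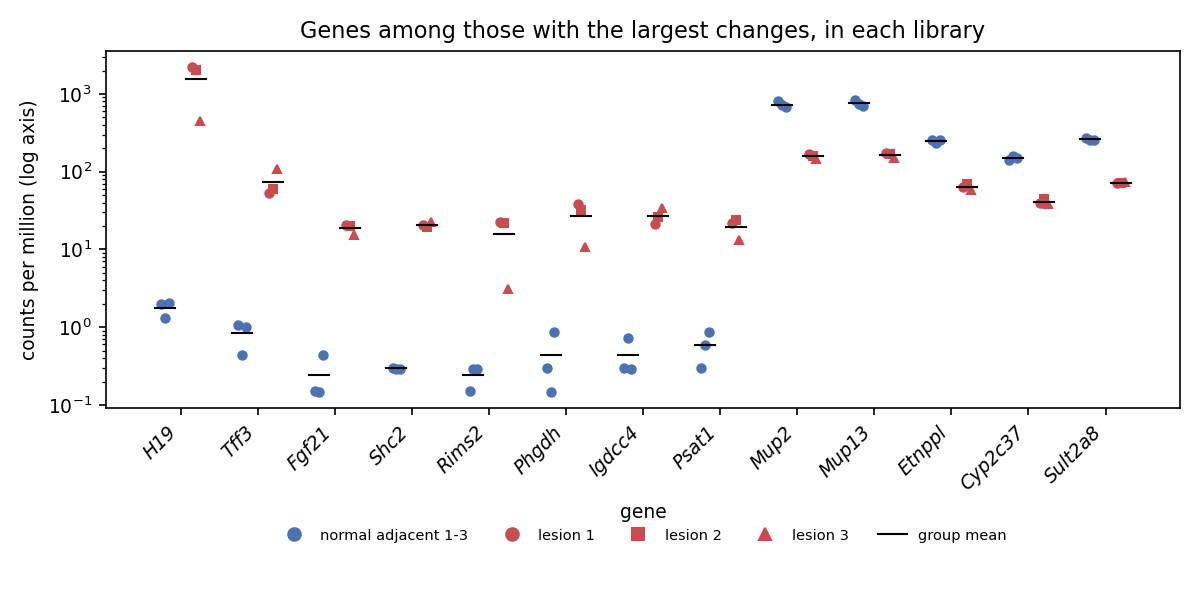
CPM (log axis) of 13 of the genes with the largest changes in each normal adjacent and lesion library, with group means as lines. H19 lies at 1.32 to 2.03 CPM in the normal libraries and at 450.3 to 2220 CPM in the lesions.

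Genes of glycogen handling changed at particular steps. The branching enzyme gene Gbe1 (Entrez 74185, chromosome 16, 70313949 to 70569720), which adds branch points to glycogen, rose from 128 ± 2.33 to 247 ± 29.2 CPM (log2 0.95, SE 0.0742, edgeR adjusted p = 6.97e-09). The glucose-6-phosphatase gene G6pc (Entrez 14377, chromosome 11, 101367716 to 101377903), which frees glucose for export, fell from 856.1 ± 18.8 to 515.9 ± 43.8 CPM (log2 -0.73, SE 0.0618, edgeR adjusted p = 1.41e-08). The main liver genes of glycogen synthesis and breakdown did not pass in the main test, though Gys2 reached an adjusted p of 0.0306 at the lowest over all alternatives. Gys2, liver glycogen synthase, was at 254 ± 9.83 and 250.1 ± 7.37 CPM (edgeR adjusted p = 0.793), and Pygl, liver glycogen phosphorylase, at 574.3 ± 11.4 and 581.6 ± 5 CPM (edgeR adjusted p = 0.815). Slc37a4, the glucose-6-phosphate transporter, was at 137.2 ± 3.54 and 153 ± 3.99 CPM (edgeR adjusted p = 0.0513). With libraries left out its result depended on the library (edgeR adjusted p from 0.00727 to 0.351). Epm2a, the glycogen phosphatase laforin, was at 1.93 ± 0.556 and 1.53 ± 0.301 CPM (SE 0.375 on the log2 scale, edgeR adjusted p = 0.522), and no change was detectable at this low level.

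The glycogen synthesis list also holds genes that are not synthesis enzymes, such as Stbd1 and Epm2a. Of its 13 tested genes, 4 rose and 9 did not pass, with the same 4 adjusted over the list alone. Besides Gbe1 these were Ugp2 (log2 0.34), Stbd1 (0.33) and the glycogenin gene Gyg (0.72). Without lesion 3 the Ugp2 change was 0.22, and without normal 1 or 2 the Gyg call was lost (edgeR adjusted p = 0.0521 and 0.0563), as it was with DESeq2 (adjusted p = 0.0519) and without replicate 1 or 2 of both groups (edgeR adjusted p = 0.112 and 0.0917). The Stbd1 call was lost on the scale of library size alone (edgeR adjusted p = 0.0573) and without replicate 2 (edgeR adjusted p = 0.0649), and the Ugp2 call on unfiltered FPKM (limma adjusted p = 0.0632). Of 12 genes of glycogen breakdown and glucose release, 4 rose, G6pc fell and 7 did not pass, with 5 higher and 1 lower adjusted over the list alone. Pygb, the brain-type phosphorylase, rose from 11.8 ± 1.26 to 55 ± 6.11 CPM (log2 2.21, edgeR adjusted p = 1.28e-11), and the lysosomal glucosidase gene Gaa rose by 0.41. Neither list passed its test (camera adjusted p = 0.098 for synthesis and 0.096 for breakdown). With fry, which does not compare a list with other genes, both were called higher (fry adjusted p = 0.0121 and 0.00237). Fry called 19 lists higher and 14 lower, where the main test called 13 and 13, so its calls are not particular to glycogen genes. It added 9 lists to the main calls, glycolysis, the clock and endothelial markers among them. It lost the NRF2 and complement lists (fry adjusted p = 0.0501 and 0.0564). Without a count filter the breakdown list was called higher (camera adjusted p = 0.0494). The median difference of the glycogen synthesis list from the normal mean was 0.01, 0.20 and 0.41 on the log2 scale in lesions 1 to 3, and with lesion 3 alone, an alternative chosen after seeing the data, the list was called higher (camera adjusted p = 0.0176). Its median was 0.24, and 0.37 without lesion 1, 0.39 without replicate 1 and 0.135 without replicate 3 of both groups.

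**Figure D2:**
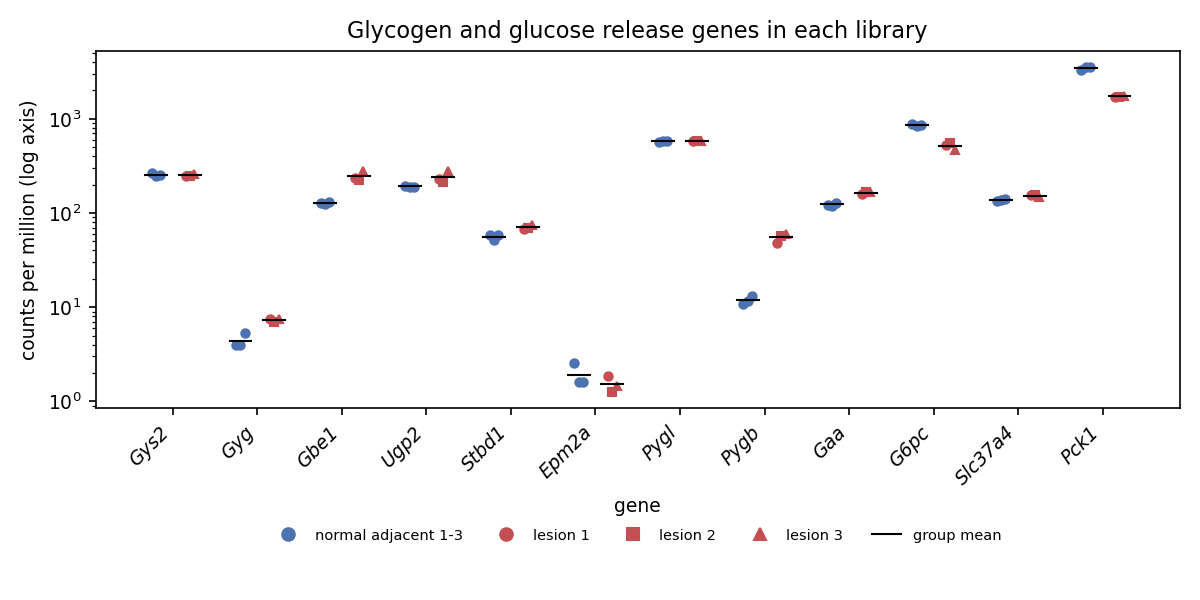
CPM (log axis) of 12 genes of glycogen handling and glucose release in each library, with group means as lines. Gys2 and Pygl overlap between the groups, while Gbe1 and Pygb lie higher and G6pc and Pck1 lower in all 3 lesion libraries.

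Hippo pathway genes went both ways. The kinase genes Stk3 and Stk4, the mammalian Hippo kinases, did not pass, at 10.9 ± 2.67 and 10.6 ± 1.46 CPM for Stk3 (edgeR adjusted p = 0.906) and 24.6 ± 1.2 and 24.1 ± 1.6 CPM for Stk4 (edgeR adjusted p = 0.849). Yap1, the growth-promoting coactivator that the pathway restrains, rose from 75.6 ± 4.33 to 88.5 ± 1.32 CPM (log2 0.23, SE 0.0709, edgeR adjusted p = 0.016). That call was lost on the scale of library size alone (edgeR adjusted p = 0.354), with DESeq2 (adjusted p = 0.0722), and without normal 1 or lesion 1 (edgeR adjusted p = 0.0984 and 0.0523). Of 26 tested pathway components 5 rose, 4 fell and 17 did not pass, with 5 and 3 adjusted over the list alone (camera adjusted p = 0.27). With fry that list was called higher (fry adjusted p = 0.0437). The angiomotin gene Amot rose by 2.34 and Map4k4 by 0.60, while Taok1 and Mob1b had log2 fold changes of -0.38 and -0.53. Of 19 YAP and TAZ targets 7 rose, 4 fell and 8 did not pass, with 8 and 4 adjusted over the list alone (camera adjusted p = 0.48). The target Ctgf rose by 1.26, and Axl fell by 0.56 on the log2 scale. The Ctgf call was lost without replicate 1 or 2 of both groups (edgeR adjusted p = 0.0503 and 0.0523), on unfiltered FPKM (limma adjusted p = 0.0504), and with lesion 3 alone, where the change was 0.447 (edgeR adjusted p = 0.331).

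Most of the tested gluconeogenesis genes fell, while the lipid synthesis lists tested as higher with fewer members rising than not. Of 12 gluconeogenesis genes 9 fell, 2 rose and 1 did not pass, the same adjusted over the list alone (camera adjusted p = 0.00024, adjusted p = 0.178 with an estimated correlation). Pck1 went from 3454 ± 124.3 to 1729 ± 32.8 CPM (edgeR adjusted p = 1.05e-11), and Got1 fell by 1.23 on the log2 scale. Of 24 glycolysis genes 8 rose, 2 fell and 14 did not pass, with 9 and 4 adjusted over the list alone. Gpi1 rose by 1.20 and Aldoa by 0.52. The glycolysis list missed its threshold (camera adjusted p = 0.082) and passed without lesion 1 or lesion 3 (camera adjusted p = 0.0489 and 0.0371) and with DESeq2 (camera adjusted p = 0.0291). Of 11 pentose phosphate genes 6 rose, 2 fell and 3 did not pass, the same adjusted over the list alone, with Pgd up by 1.71 and Tkt by 0.49 (camera adjusted p = 0.036, adjusted p = 0.179 with an estimated correlation). That list's call was lost without normal 2 or normal 3 (camera adjusted p = 0.058 and 0.0579) and with limma-voom (camera adjusted p = 0.0967).

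In lipid synthesis, 9 of 20 fatty acid genes rose, 5 fell and 6 did not pass, the same adjusted over the list alone (camera adjusted p = 0.00028, adjusted p = 0.111 with an estimated correlation). Fasn, the fatty acid synthase gene, went from 3072 ± 83 to 7743 ± 347.5 CPM (log2 1.33, SE 0.0531, edgeR adjusted p = 2.26e-13). Acaca rose by 1.15, Gpam by 1.13 and Acly by 0.86. Of 24 cholesterol synthesis genes 10 rose, 1 fell and 13 did not pass, with 12 and 1 adjusted over the list alone (camera adjusted p = 2e-06, adjusted p = 0.422 with an estimated correlation). Mvd rose by 2.17 and Stard4 by 0.37. The list's median difference from the normal mean was 1.71 on the log2 scale in lesion 3 and 0.71 and 0.68 in lesions 1 and 2. Of 25 fatty acid oxidation genes 16 fell and 9 did not pass, with 19 lower adjusted over the list alone (camera adjusted p = 0.00012, adjusted p = 0.216 with an estimated correlation). Cpt2, of the mitochondrial carnitine shuttle, fell by 0.59 on the log2 scale. Of 59 nuclear genes of oxidative phosphorylation 48 fell and 11 did not pass, with 51 lower adjusted over the list alone (camera adjusted p = 9.8e-12, adjusted p = 0.179 with an estimated correlation). Cox5b fell by 0.92 and Ndufa4 by 0.81 on the log2 scale.

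Most genes of the tested hepatocyte functions were lower, on both sides of the lobule. Of 25 genes of the urea cycle and amino acid breakdown 19 fell and 6 did not pass, the same adjusted over the list alone (camera adjusted p = 4.3e-22, adjusted p = 0.0733 with an estimated correlation). Tat, which degrades tyrosine, went from 1279 ± 11.8 to 488.5 ± 18.1 CPM (log2 -1.39, SE 0.054, edgeR adjusted p = 1.81e-13), and Oat and Hpd had log2 fold changes of -1.44 and -1.29. Of 31 cytochrome P450 genes 20 fell, 2 rose and 9 did not pass, with 23 and 3 adjusted over the list alone (camera adjusted p = 1.2e-17, adjusted p = 0.0135 with an estimated correlation). Cyp2e1 went from 3767 ± 29.7 to 1418 ± 51.6 CPM (log2 -1.41, edgeR adjusted p = 1.07e-13), while Cyp2b9 rose by 2.31. Of 26 Wnt targets and pericentral genes 18 fell, 3 rose and 5 did not pass, the same adjusted over the list alone (camera adjusted p = 2e-18, adjusted p = 0.0135 with an estimated correlation). Glul, the glutamine synthetase gene of pericentral hepatocytes, fell from 1181 ± 11.6 to 656.1 ± 57.7 CPM (log2 -0.85, SE 0.061, edgeR adjusted p = 1.29e-09), and the glutamate transporter gene Slc1a2 fell by 1.43 on the log2 scale. Of 23 periportal genes 14 fell, 3 rose and 6 did not pass, the same adjusted over the list alone (camera adjusted p = 3.2e-10, adjusted p = 0.179 with an estimated correlation). The periportal genes Cps1 and Cyp2f2 fell by 1.02 and 0.94 on the log2 scale. The periportal list had a median of -0.717 and a mean of -0.301. Of its 23 tested genes 11 also stand in another list, as do 7 of the 25 urea cycle genes, so these lists are not independent.

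Bile acid genes fell in 15 of 19 cases, with 3 higher and 1 not passing, the same adjusted over the list alone (camera adjusted p = 1.5e-10, adjusted p = 0.0213 with an estimated correlation). The uptake transporter gene Slco1b2 fell by 1.49, the export pump gene Abcb11 by 0.94 and Cyp27a1 by 0.90 on the log2 scale. Of 26 male-biased liver genes 22 fell, 3 rose and 1 did not pass, with 22 and 4 adjusted over the list alone (camera adjusted p = 8.5e-26, adjusted p = 0.0135 with an estimated correlation). Mup3 fell by 1.52, Slco1a1 by 1.69 and Nudt7 by 1.43 on the log2 scale, and Serpina1e, a member of a near-identical family, rose by 1.33. Of 19 female-biased genes 8 fell, 4 rose and 7 did not pass, the same adjusted over the list alone (camera adjusted p = 0.86). The female-biased median was -0.10 and the mean 0.15. Without lesion 3 the female-biased list was called higher (camera adjusted p = 0.00433) at a median of -0.08, so its test and its median differed in sign.

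Secreted plasma proteins moved in opposite directions. Of 27 acute phase genes 19 fell, 4 rose and 4 did not pass, the same adjusted over the list alone (camera adjusted p = 3.2e-07, adjusted p = 0.0841 with an estimated correlation). The serum amyloid genes Saa2 and Saa1 fell by 1.83 and 1.63 and Orm1 by 1.16 on the log2 scale. Of 34 complement and coagulation genes 14 fell, 5 rose and 15 did not pass, with 15 and 6 adjusted over the list alone (camera adjusted p = 0.041, adjusted p = 0.672 with an estimated correlation). C9 fell by 1.55 and C8b by 0.82 on the log2 scale, and the antiplasmin gene Serpinf2 rose by 1.07. That list's call was lost without normal 2 or 3 or lesion 1 or 2 (camera adjusted p = 0.0594, 0.0582, 0.138 and 0.0948) and with the replicate block (camera adjusted p = 0.0564), and its median moved from -0.06 to -0.13 without lesion 3 and to -0.01 without lesion 1 or 2. Of 27 other hepatocyte secreted proteins and regulators 10 rose, 10 fell and 7 did not pass, the same adjusted over the list alone (camera adjusted p = 0.11). The list was called higher without lesion 3 (camera adjusted p = 0.0295) and with DESeq2 (camera adjusted p = 0.0342). Apoa1 went from 2803 ± 41.5 to 8103 ± 624.1 CPM (log2 1.53, edgeR adjusted p = 1.28e-13) and the fetuin gene Ahsg rose by 1.22, while Apoa2 and Apoc1 fell by 0.68 and 0.55 on the log2 scale.

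Most of the tested cell cycle and RAS response genes were higher. Of 37 cell cycle genes 31 rose and 6 did not pass, with 35 higher adjusted over the list alone (camera adjusted p = 1.8e-13, adjusted p = 0.216 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, went from 8.82 ± 0.952 to 29.8 ± 3.02 CPM (log2 1.76, SE 0.133, edgeR adjusted p = 2.78e-09), and the replication licensing genes Mcm5 and Mcm2 rose by 2.24 and 1.76. Of 17 RAS and MAPK response genes 10 rose and 7 did not pass, the same adjusted over the list alone (camera adjusted p = 4.5e-09, adjusted p = 0.12 with an estimated correlation). Egr1, an immediate early transcription factor gene, went from 10.9 ± 1.04 to 262.6 ± 28.2 CPM (log2 4.59, SE 0.101, edgeR adjusted p = 3.14e-16), and the MAP kinase phosphatase genes Dusp4 and Dusp6 rose by 2.62 and 1.30. Of 18 immediate early and heat shock genes 8 rose, 1 fell and 9 did not pass, with 11 and 1 adjusted over the list alone (camera adjusted p = 2e-06), and Junb and Ier2 rose by 0.95 and 0.97. Its median was 0.41, and 0.22 without lesion 3. The adjusted p with an estimated correlation was 0.05, just under the threshold before rounding.

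Of 21 tested liver tumour and fetal liver markers 12 rose, 2 fell and 7 did not pass, the same adjusted over the list alone (camera adjusted p = 4.1e-05, adjusted p = 0.178 with an estimated correlation). Afp, the fetal albumin-like protein, rose from 4.84 ± 1.09 to 25.4 ± 10.6 CPM (log2 2.38, SE 0.395, edgeR adjusted p = 0.00592), and Akr1c18 and Golm1 rose by 3.40 and 1.21. Gpc3, a tumour marker on the cell surface, was under the expression filter and untested, with 4, 4 and 2 counts in the normal regions and 6, 14 and 278 in lesions 1 to 3. Of 24 NRF2 targets, an oxidative stress group, 9 rose, 3 fell and 12 did not pass, the same adjusted over the list alone (camera adjusted p = 7.9e-05, adjusted p = 0.492 with an estimated correlation). Srxn1 rose by 2.66, Osgin1 by 1.93 and Txnrd1 by 0.82, and the haem oxygenase gene Hmox1 fell by 0.45 on the log2 scale. The NRF2 list's median was 0.89, and 0.57 without lesion 3. Of 27 genes of the ER and integrated stress responses 12 rose, 6 fell and 9 did not pass, with 13 and 6 adjusted over the list alone (camera adjusted p = 0.00055, adjusted p = 0.111 with an estimated correlation). Beside Fgf21 and Psat1, the asparagine synthetase gene Asns rose by 1.77 and the transcription factor gene Atf5 by 1.39.

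**Figure D3:**
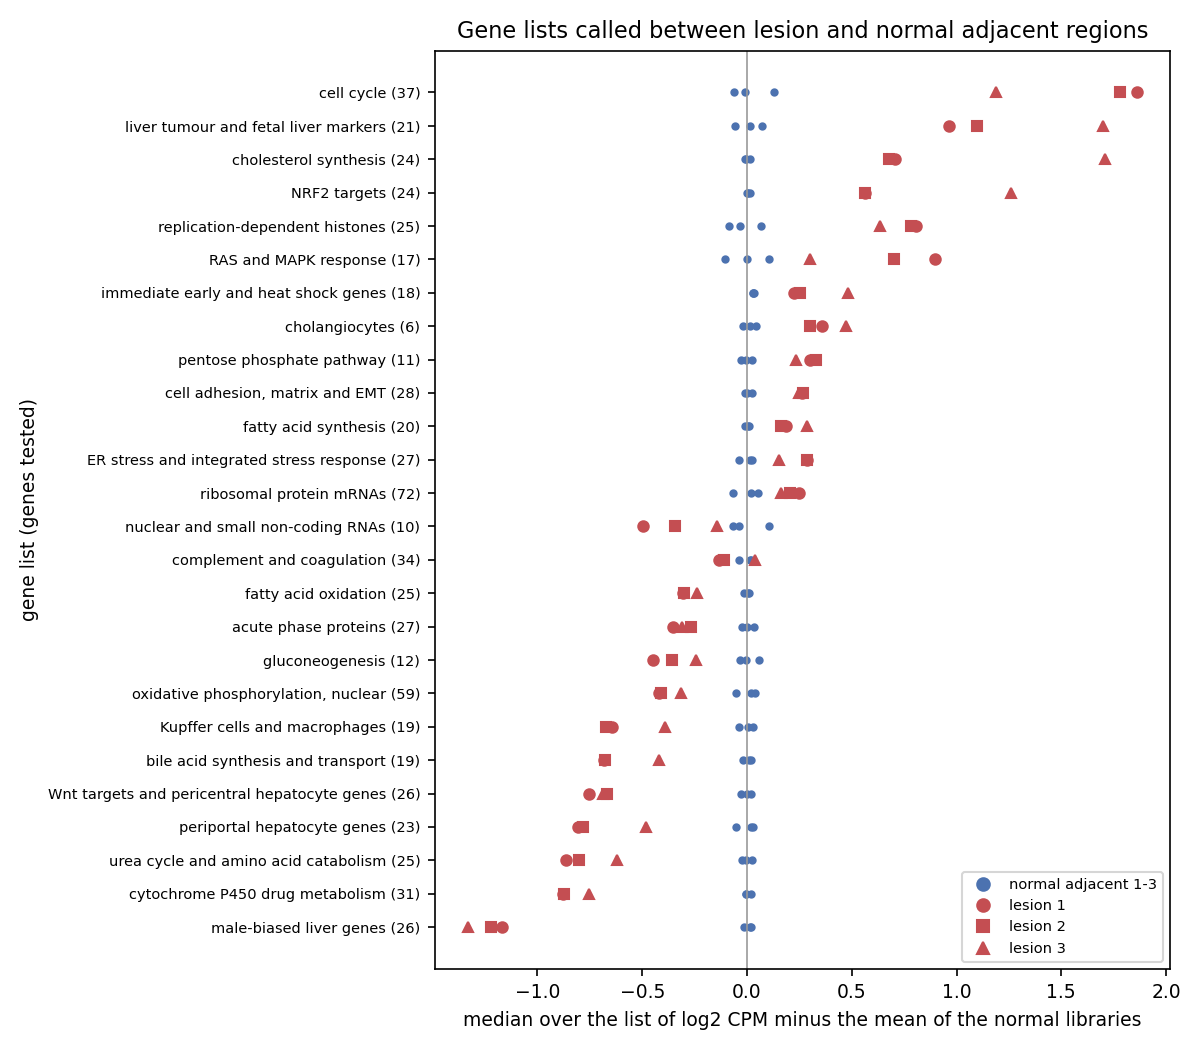
Median over each called gene list of log2 CPM minus the mean of the normal libraries, for the 3 normal and 3 lesion libraries, with the number of genes tested in brackets. In cholesterol synthesis lesion 3 lies at 1.71 and lesions 1 and 2 at 0.71 and 0.68, and in the male-biased genes the lesion libraries lie from -1.33 to -1.17.

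Markers of the other liver cells did not move together. Of 19 markers of Kupffer cells, the resident macrophages of the liver, 16 fell and 3 did not pass, the same adjusted over the list alone (camera adjusted p = 2.5e-08, adjusted p = 0.111 with an estimated correlation). Timd4 and Vsig4 fell by 1.17 and 1.13 on the log2 scale, and Cd163 went from 102.7 ± 6.07 to 51.4 ± 3.7 CPM (edgeR adjusted p = 4.32e-09). Of 26 endothelial markers 9 rose, 4 fell and 13 did not pass, with 9 and 5 adjusted over the list alone (camera adjusted p = 0.45). Esm1 rose by 2.21 and Lyve1 by 0.96, and Fcgr2b fell by 0.55 on the log2 scale. Of 21 stellate cell and fibroblast markers 4 rose, 6 fell and 11 did not pass, with 4 and 7 adjusted over the list alone (camera adjusted p = 0.65). The fibrillar collagen genes Col1a2 and Col3a1 rose by 1.08 and 0.82, and Colec10 and Hgf fell by 1.40 and 0.98 on the log2 scale. Of 28 genes of adhesion, matrix and epithelial-mesenchymal transition 13 rose, 5 fell and 10 did not pass, with 13 and 6 adjusted over the list alone (camera adjusted p = 0.0047, adjusted p = 0.111 with an estimated correlation). Spp1, the osteopontin gene, went from 17.8 ± 1.78 to 123.4 ± 19.3 CPM (log2 2.80, edgeR adjusted p = 9.7e-11). Of 6 tested cholangiocyte markers 3 rose, among them Spp1 and Sox9, and 3 did not pass, the same adjusted over the list alone (camera adjusted p = 0.002, adjusted p = 0.111 with an estimated correlation), and 2 of the 6 also stand in another list.

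Blood cell markers were scarce. Of 7 T and NK cell markers 1 fell, and 0 passed adjusted over the list alone (camera adjusted p = 0.79). That gene, Themis, fell by 0.96 on the log2 scale (edgeR adjusted p = 0.0432), and the call was lost without normal 1 or 2 or any lesion library except lesion 1 (edgeR adjusted p from 0.0995 to 0.171). Among lists too short for a list test, 2 of 4 B and plasma cell markers fell, Bank1 and Jchain, the same adjusted over the list alone. Without normal 1 or lesion 1 neither passed (edgeR adjusted p = 0.0712 and 0.0939 for Bank1, 0.205 and 0.117 for Jchain), and Bank1 was also lost without normal 2 or lesion 2 (edgeR adjusted p = 0.0983 and 0.0807). The erythroid gene Alas2 fell by 1.02 on the log2 scale, 1 of 2 tested markers, and both tested adipocyte markers, Cidec and Cfd, fell by 0.79 and 1.38, the same counts adjusted over each list alone. The Cfd call was lost without normal 1 (edgeR adjusted p = 0.0838) and the Cidec call without replicate 1 of both groups (edgeR adjusted p = 0.0736). With DESeq2 the Themis, Bank1 and Jchain calls were lost (adjusted p = 0.147, 0.0545 and 0.0935). The only tested neutrophil marker, Csf3r, was at 10.2 ± 2.25 and 9.05 ± 0.559 CPM (edgeR adjusted p = 0.473). Mesothelial and mitochondrially encoded genes had no tested member and were not analysed here.

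RNA classes listed as quality checks also differed, and whether RNA quality differed was not tested. Cell cycle genes rose too (31 of 37), so a rise of replication-dependent histones need not mark quality. Of 72 ribosomal protein genes 38 rose, 3 fell and 31 did not pass, the same adjusted over the list alone, with a median of 0.20 (camera adjusted p = 0.00016, adjusted p = 0.326 with an estimated correlation). Rpl13 and Rpl10a rose by 0.66 and 0.60. Of 25 replication-dependent histone genes 19 rose and 6 did not pass, the same adjusted over the list alone (camera adjusted p = 8.9e-06, adjusted p = 0.32 with an estimated correlation), with Hist1h3i up by 1.79. Of 10 nuclear and small non-coding RNAs 4 fell, 2 rose and 4 did not pass, the same adjusted over the list alone. The nuclear RNA Neat1 went from 5686 ± 203.9 to 2723 ± 109.7 CPM (log2 -1.06, edgeR adjusted p = 6.21e-12), and Rpph1 and Rmrp fell by 1.02 and 0.94 on the log2 scale. That list tested as lower (camera adjusted p = 0.01, adjusted p = 0.259 with an estimated correlation), with a mean of -0.18 and a median of 0.09. The median was -0.06 on the scale of library size alone, -0.05 without normal 2, 0.06 without normal 3, -0.33 without lesion 3 and 0.25 and 0.27 without normal 1 and lesion 1. Leaving small RNA out ended the call (camera adjusted p = 0.358).

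Other lists did not pass as lists. Of 31 lysosome and autophagy genes 7 rose, 8 fell and 16 did not pass, the same adjusted over the list alone (camera adjusted p = 0.78), with the autophagy kinase gene Ulk1 up by 1.09 and Lamp2 at -0.78. Of 19 insulin and IGF genes 5 rose, 5 fell and 9 did not pass, with 5 and 7 adjusted over the list alone (camera adjusted p = 0.65). Igf1 fell from 749 ± 34.5 to 387.4 ± 14.5 CPM (log2 -0.95, edgeR adjusted p = 9.77e-11) and Igfbp1 rose by 1.38. That list holds H19 (log2 9.77), whose change weighs heavily on the list mean. The list median was -0.10 and the mean 0.48. Without lesion 3 the list was called higher (camera adjusted p = 0.00364) at a median of -0.12. Of 20 p53 targets 5 rose, 5 fell and 10 did not pass, with 5 and 6 adjusted over the list alone (camera adjusted p = 0.93), with Tnfrsf10b up by 1.55 and Trp53inp1 at -0.66. Of 18 clock genes 6 rose, 4 fell and 8 did not pass, with 7 and 5 adjusted over the list alone (camera adjusted p = 0.21), and Dbp, Per3 and Per2 rose by 0.71, 0.65 and 0.55. Of 21 iron and haem genes 9 fell, 3 rose and 9 did not pass, the same adjusted over the list alone (camera adjusted p = 0.1, and 0.0127 without lesion 3), with Alas1 at -0.82 and the haemojuvelin gene Hfe2 at 0.73.

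Immune and oxygen response lists did not pass as lists. Of 28 interferon response genes 1 rose, 4 fell and 23 did not pass, and 0 passed adjusted over the list alone (camera adjusted p = 0.78). At an unadjusted level the lowest p in that list was 0.00424, for Irf7, with a log2 fold change of -0.40. Without lesion 3 the log2 fold change of Irf7 was -0.258, and without normal 2 or 3 its call was lost (edgeR adjusted p = 0.0563 and 0.0744). Of 16 genes of antigen presentation 3 rose, 3 fell and 10 did not pass, the same adjusted over the list alone (camera adjusted p = 0.86), with B2m at -0.43 and Tap2 at 0.44. Of 14 hypoxia response genes 1 rose, 3 fell and 10 did not pass, with 1 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.65). The risen gene, Vegfa, rose by 0.21 (edgeR adjusted p = 0.0111), a call lost without normal 2 (edgeR adjusted p = 0.078) and on the scale of library size alone (edgeR adjusted p = 0.407).

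The authors' deposited table gave an adjusted p for 14151 genes, with 1717 higher and 1580 lower in the lesions. Of these, 1585 were also higher and 1559 also lower in the edgeR test, and 0 were called in opposite directions. The authors' deposited table gave H19 a log2 fold change of 9.78 and Gpc3 4.88 (SE 1.55), the latter without an adjusted p.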

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

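The alternatives with near-identical libraries summed and with lesion 3 alone were chosen after the data were seen. Across all alternatives no gene called in the main test was called in the opposite direction. Library size alone gave 1474 higher and 3615 lower genes, since it moved the median of all genes. Requiring a log2 fold change of at least 1 left 541 and 303 genes, and an estimated correlation left 1 higher and 4 lower lists, where the main tests gave 2340, 2296, 13 and 13. Leaving out a library or a replicate number gave 1349 to 2798 higher genes, 1352 to 2796 lower genes, 12 to 17 higher lists and 11 to 14 lower lists. With both libraries of a number left out, 2 stood against 2, and without replicate 1 the counts were 1423 and 1505. In these fits the list median ran from -0.158 to -0.0368 for insulin and IGF signalling and from -0.352 to -0.0834 for female-biased genes. Both lists turned to a higher call without lesion 3 (camera adjusted p = 0.00364 and 0.00433) and without replicate 3 (camera adjusted p = 0.0085 and 0.0161), at medians of -0.121 and -0.0834 and of -0.0632 and -0.199, and the cause was not tested.

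The remaining settings kept each count within 1.5 times the main one. DESeq2 gave 1761 higher and 1661 lower genes, limma-voom 2259 and 2244, limma-trend on log2(FPKM + 1) 1927 and 1965, and the length correction 2079 and 2645. Pairing by replicate number left no sign in the deviations from the group means. Their correlations were 0.011, -0.021 and -0.022 for same-numbered regions and -0.016 to 0.036 for the others. With 3 libraries per group and no animal in the labels, these values cannot show whether same-numbered regions share a mouse. A fit with the replicate block gave 2293 higher and 2233 lower genes and 12 and 12 lists, without the pentose phosphate (camera adjusted p = 0.0502) and complement lists. Chi-square per gene was 1.37 between normal 2 and 3 and 1.57 between lesion 1 and 2, above sampling noise but below the 3.15 to 11.2 of other pairs within groups. With these pairs summed, 2 against 2, 1607 genes were higher and 1595 lower, of which 1569 and 1579 were called in the main test. H19 was then lost (edgeR adjusted p = 0.0831; 0.0965 at most over all settings), as it was without replicate 1 or 2. Lesion 3 alone, with the spread taken from the normal regions, gave 2057 and 1806 genes. The adhesion, cholangiocyte and nuclear RNA lists lost their calls on FPKM (camera adjusted p from 0.0615 to 0.481 where lost). Depth limits genes near the filter, such as Gpc3, Epm2a and the blood cell markers.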

Other observations

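The tests weighing patterns in this part were chosen after the result was seen, while the other splits of the libraries, the gene length correction and the fits without a library were planned as settings. The 3 gene lists on serine synthesis, growth hormone signalling and imprinted genes, and the single genes named here, were also chosen after their values were seen. The list of serine synthesis and mitochondrial one-carbon genes also holds amino acid transporter genes, Asns and the proline synthesis gene Aldh18a1. Of its 13 tested genes, 3 were named by the fixed rule (Phgdh, Psat1 and Asns) and are left out of the counts here. Of the other 10, 6 rose, 0 fell and 4 did not pass. The 6 were Psph, Mthfd2 and Mthfd1l of the named pathways, and the transporter genes Slc7a1 and Slc1a4 and Aldh18a1 from outside them. The list test, adjusted over the 3 added lists, gave a camera adjusted p of 3.3e-05 (adjusted p = 0.03 with an estimated correlation). The list was still put together on these data, so that p is no independent evidence. Psph, the last enzyme of serine synthesis, rose by 1.95 on the log2 scale, the formate-producing gene Mthfd1l by 2.05 and the proline synthesis gene Aldh18a1 by 2.28, with all 3 lesion libraries above all 3 normal libraries. Of the 24 stress response genes outside the serine list, 9 rose, among them Fgf21 and Atf5, and 6 fell.

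Growth hormone signalling genes gave 4 lower, 1 higher and 6 not passing of 11 (camera adjusted p = 0.02, adjusted p = 0.17 with an estimated correlation), and the list did not pass without Igf1, which the fixed rule had named (camera adjusted p = 0.17). The receptor gene Ghr fell by 1.05 and its target Igf1 by 0.95 on the log2 scale, while the feedback inhibitor gene Cish rose by 0.82. Of 10 tested imprinted growth genes 4 rose, 1 fell and 5 did not pass (camera adjusted p = 0.17). H19 and Igf2 share an imprinted locus, yet Igf2 was at 2.47 ± 0.79 and 2.95 ± 0.72 CPM (log2 0.26) and did not pass. Of the Y-linked genes Uty and Eif2s3y had log2 fold changes of -0.52 and -0.59, Ddx3y -0.22 and Kdm5d 0.17, the last not passing. In lesion 3, Gpc3, A2ml1 and Rtn4rl2 had 278, 316 and 110 counts and at most 18 in any other library. No other library had a gene with at least 100 counts there and at most 20 elsewhere.

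Lesion 3 stood apart from lesions 1 and 2. A difference in depth as the cause is argued against by its total of 7.37 M counts, which lies between the 7.29 M and 7.41 M of lesions 1 and 2. Admixture of normal tissue as the whole cause is argued against by 77 genes in which lesion 3 lay at least 0.5 log2 farther from normal than both others, where lesion 1 lay beyond lesion 2 in 6 and lesion 2 beyond lesion 1 in 11. It lay nearer to normal in 104 of the 3639 genes compared. Whether lesions 1 and 2 come from the same lesion or RNA cannot be told apart from 2 similar lesions, at a chi-square of 1.57 per gene, because the labels name no animal or lesion, and a difference between lesions may remain.

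Kupffer cell markers were lower in all 3 lesions, with list medians of -0.645, -0.673 and -0.392. A higher share of hepatocyte RNA would lower endothelial markers alike, but their median lay 0.646 above that of the Kupffer markers (permutation p over genes = 0.00013, adjusted p = 0.00026), though genes are not independent replicates. The stellate median lay 0.248 above (permutation p = 0.19, adjusted p = 0.19), but the stellate median itself was -0.486, -0.438 and -0.0554 in lesions 1 to 3, and ran from -0.543 (without lesion 3) to -0.106 (without replicate 1 of both groups) in the fits with libraries left out. With the gene length correction 16 of the 19 markers were still lower and the list kept its call at the preset correlation (camera adjusted p = 3.91e-08), a call that is lost without the correction at an estimated correlation (adjusted p = 0.111). The endothelial list held genes that rose (9, among them Esm1) and genes that fell (4), so its median is a loose measure of endothelial share. A higher share of hepatocyte RNA is thus not excluded, as the stellate markers did not differ detectably from the Kupffer markers. Fewer Kupffer cells in the lesions or less of these transcripts per cell may also account for the lower markers. Of the 19 markers, 1 also stands in another list.

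Male-biased genes were lower in all 3 lesions. Reads shared between Mup copies would leave other members in place, but 17 of the 20 members other than Mup genes were lower. A loss of all hepatocyte transcripts alike would bring secreted proteins and regulators down too, but their median minus 1 SD of the members was -0.54 against a male-biased median of -1.34. Other hepatocyte lists did fall, with medians of -0.824 (cytochrome P450), -0.735 (urea cycle), -0.717 (periportal), -0.709 (pericentral) and -0.577 (bile acid). A loss of many hepatocyte functions that takes in the male-biased genes therefore stays open. A switch to the female-type programme cannot be told apart, because the female-biased genes went both ways (their median plus 1 SD of the members was 1.57) and the list was called higher without lesion 3 (camera adjusted p = 0.00433) and without replicate 3 (camera adjusted p = 0.0161). Reduced growth hormone action may be one explanation and stays open, since Ghr and Igf1 fell, Cish rose, Socs2 did not pass and the growth hormone list lost its call with an estimated correlation (adjusted p = 0.17).

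Gain or loss of a whole chromosome in most lesion cells was looked for as a negative check. Over 20 chromosomes (1 to 19 and X) and genes of at least 16 CPM, the largest median shift of any lesion library was 0.11 in size. That is below the 0.32 that 5 copies in place of 4 would give. The Y chromosome was left out of this check. Its genes Uty, Eif2s3y and Ddx3y were lower (log2 -0.52, -0.59 and -0.22), while Kdm5d did not pass (0.17). A change in the copy number of Y was not tested. Of the 10 splits of the 6 libraries into 3 and 3, only the real one, 1 of 10, gave as many genes (4636, highest other 0) or as many lists (26, highest other 17). With 10 splits the share cannot go under 0.1, so they are too few for a test.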
